A study of Mus musculus with 16 samples.

How the data were processed

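Whole aorta was profiled in 16 individual apolipoprotein E-deficient mice at 18 weeks of age, with 1 Affymetrix array per mouse. Mice without apolipoprotein E develop atherosclerosis. Per the labels, all mice ate a high fat diet for 10 weeks, starting at 8 weeks of age. Diabetes was induced at 6 weeks of age with streptozotocin, a toxin of the insulin-producing beta cells. Ruboxistaurin (RBX, also LY333531), an inhibitor of protein kinase C beta, was mixed into the diet of some of the mice, at a dose not given in the sources used here. The sample titles gave 4 groups of 4 mice: non-diabetic, non-diabetic with RBX, diabetic, and diabetic with RBX. Replicate numbers 1 to 4 were taken from the titles.

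Per the labels' protocols, total RNA was extracted with Trizol, and biotinylated cRNA was prepared from 2 ug of it. Per the submitters' processing notes, the signals were made with MAS5, whose version is not given in the sources used here. The deposited values were intensity on a linear scale for 45101 probe sets per array, from a lowest value of 0.7 upwards. The mean of each array after leaving out 2% of the values at each end was 1500.01, so the authors had scaled every array by 1 factor to the same trimmed mean. Detection calls and background settings were not used here, so no probe set was called absent. Such a trimmed scaling fixes the average signal of each array, and a change in the brightest probe sets is therefore read against that average.

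Gene names came from GEO's annotation of the platform. Of the probe sets, 34958 had 1 gene symbol, 932 had several and were not named, and 9211 were unnamed here; 64 were Affymetrix controls. Symbols were looked up through their Entrez identifiers in a mouse RefSeq gene table of assembly GRCm38.p6, which held 99.4% of the probe sets with 1 symbol and changed 0 of them. Values were taken to log2 with no offset. Probe sets were kept where their mean log2 signal lay above the median over all probe sets, a linear signal of 381.5. For each gene the kept probe set with the highest mean was used, which left 11042 genes out of 18194 symbols. Of the genes named in the text, 72 had another measured probe set, and in 195 of 210 comparisons it moved the same way. In 5 of the others, on 4 genes, it moved the opposite way at an unadjusted p under 0.05, which is said where these genes are named.

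Differences were tested with limma 3.58.1 in R 4.3.3 (with data.table at version 1.17.8) on all 16 arrays, with a mean for each of the 4 groups, 12 residual degrees of freedom, 6.2 prior degrees of freedom and an intensity trend in the empirical Bayes step. The comparisons were diabetes without RBX, RBX in diabetic mice, RBX in non-diabetic mice, diabetes with RBX, their interaction (the effect of RBX in diabetic mice minus that in non-diabetic mice), and the averaged effects of diabetes and of RBX. P-values were two-sided and adjusted by Benjamini-Hochberg over the 11042 genes of each comparison, and a gene was said to have risen or fallen when its adjusted p was under 0.05. Log2 fold changes are given with their standard error, and group levels as mean ± SD of the linear signal.

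In all, 36 gene lists of pathways and cell types were written before the data were examined, each with at least 4 measured members. They were tested with camera in limma, with a preset correlation between genes of 0.01 and again with the correlation estimated from the data, and adjusted over the 36 lists of a comparison. With the estimated correlation none of the lists passed in any comparison. Counts of members are given over all genes tested and, where said, adjusted over the list alone. Array measures were compared with exact two-sided permutation tests over the 70 assignments of 2 groups of 4, for which the smallest possible p is 0.0286.

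The genes named were set by a rule written before the data were examined. Prkcb and Apoe are always named. In each comparison of 2 groups the rule took the 10 largest rises and the 10 largest falls among genes past the threshold whose group values did not overlap. For averaged effects the direction had to hold in both strata, and for the interaction the adjusted p alone counted. Fewer than 10 were named where fewer passed. Up to 4 members with the smallest p were added from each list described. Clones, predicted genes and expressed sequence tags were counted and not named. Genes of averaged effects were named where no comparison of 2 groups had named them or as their fullest measure. Any gene named outside the rule is said to be so.

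The alternatives were quantile normalization, centring on the 75th percentile, no filter, a filter at the 70th percentile, an offset of 30.5 before log2 (the 10th percentile of all values), the mean over a gene's probe sets, all probe sets apart, no intensity trend, a robust variance, array weights, a replicate block, only the 2 groups compared, and each array left out in turn. For the agreement of both diabetes effects, the 1000 genes with the smallest averaged p were an alternative as well. A further 3 were added after seeing the data: the cre hybridisation control as a covariate, the 3' to 5' ratio of the Actb control probe sets as a covariate, and, for diabetes without RBX and RBX in diabetic mice, a fit without the 4 non-diabetic RBX arrays. The cre control is a bacteriophage transcript added to each hybridisation in a fixed amount. Where 2 comparisons shared arrays, the correlation of their effects was set against 100 simulated data sets without any effect and against the 6 ways of dividing the shared arrays.

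The procedure was checked on simulated data with 200 changed genes among 11042, drawn with the spread of the real arrays. For diabetes without RBX it recovered 32% of genes changed by log2 0.5, 76% at 1, 88% at 1.5 and 96% at 2. For RBX in diabetic mice the shares were 38%, 78%, 92% and 92%, for RBX in non-diabetic mice 26%, 76%, 92% and 94%, and for diabetes with RBX 38%, 72%, 82% and 98%. In the same order 12 of 158, 7 of 157, 6 of 150 and 8 of 153 calls were of unchanged genes. With nothing changed it called 0 genes in each. Camera found a set of 25 genes shifted by 0.5 (adjusted p = 1.22e-29) and 0 other sets. False calls from correlated genes were untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.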

Results

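Gene expression was measured in the whole aorta of 16 apolipoprotein E-deficient mice on a high fat diet, in 4 groups of 4 mice. The groups crossed streptozotocin diabetes with RBX, the inhibitor of protein kinase C beta, in the diet. Protein kinase C beta is activated by diacylglycerol, which builds up in vascular cells at high glucose, and the design asks how diabetes and its inhibition alter the atherosclerotic aorta. For each of 11042 genes 1 probe set was tested.

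The 4 non-diabetic RBX arrays stood apart from the other 12. On the first principal component, which held 30.1% of the variance, the group means were -23.5 for non-diabetic, 30.4 for non-diabetic RBX, -5.07 for diabetic and -1.81 for diabetic RBX mice. The signal of the cre hybridisation control, the highest value on 16 of 16 arrays, averaged 187700, 430027, 237370 and 274245 in the same order of groups. The log2 ratio of the 3' to the 5' control probe set of Actb, a measure of RNA integrity and labelling, averaged 1.04, 2.08, 1.34 and 1.71. None of the 80 array tests passed adjustment (21 at an unadjusted p under 0.05), the smallest adjusted p being 0.109. These were exact permutation tests, which cannot give a raw p below 0.0286. Within groups, log2 cre and the first component had r = 0.75 over the 16 arrays (permutation p = 0.013, adjusted 0.104 over 8 relations) and Spearman rho = 0.618 (permutation p = 0.0218, adjusted 0.135). Without the 2 arrays whose log2 cre lay farthest from their group mean, r was 0.617 (permutation p = 0.0735). No pair of arrays held identical values, and the highest rank correlation between arrays was 0.986.

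**Figure D1:**
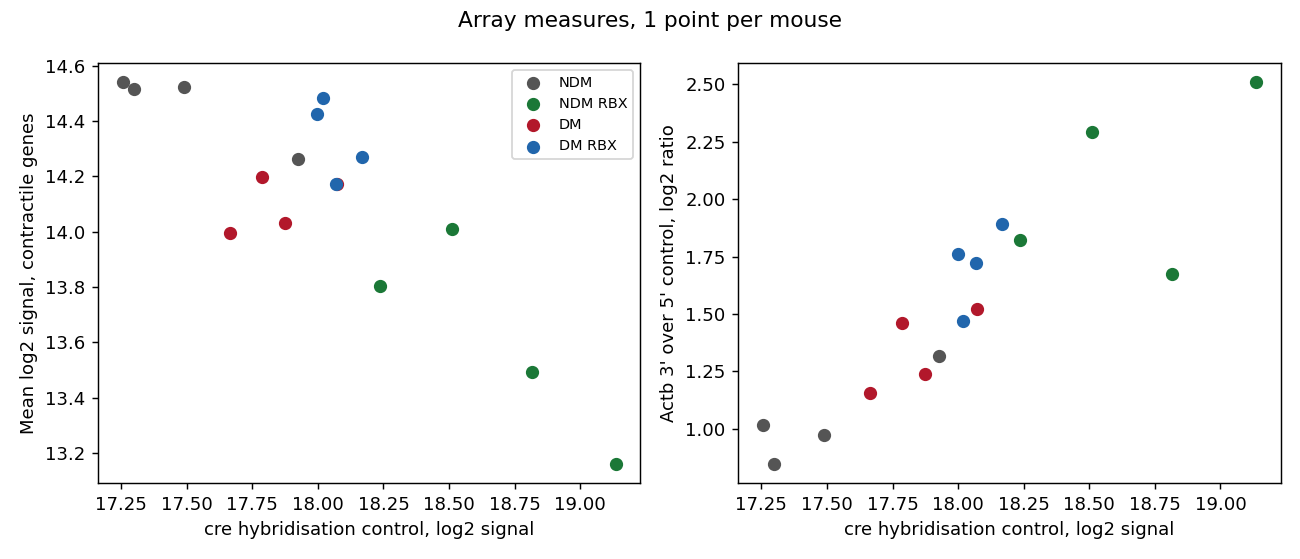
Log2 cre control signal on the x axes against the mean log2 signal of the contractile smooth muscle genes (left) and the log2 ratio of the 3' to the 5' Actb control probe set (right), 1 point per mouse, 4 mice per group. The non-diabetic RBX mice have the highest mean ratio, 2.08 against 1.04 in the non-diabetic mice without RBX.

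Apoe, the disrupted gene, was read on every array. Its signal was 493.4, 410.4, 843.2 and 435.9 in the non-diabetic mice and 790, 753.3, 635.3 and 740.8 with RBX. It was 557.3, 857.2, 1015 and 974.2 in the diabetic mice, and 453.2, 231.6, 36.9 and 406.6 in the diabetic mice with RBX. Whether the probe set lies outside the disrupted part was not checked here, so these values test no label. Apoe did not pass for diabetes without RBX (0.67, adjusted p = 0.619), for RBX in diabetic mice (-2.06, adjusted p = 0.225) or in non-diabetic mice (0.48, adjusted p = 0.536). Nor did it pass for the averaged effects of diabetes (-0.60, adjusted p = 0.649) and RBX (-0.79, adjusted p = 0.159). Without diabetic RBX mouse 3, the lowest, it was -1.25 (adjusted p = 0.283) for RBX in diabetic mice, and -0.20 (adjusted p = 0.845) and -0.38 (adjusted p = 0.216) for these averages. Prkcb, which encodes the kinase that RBX inhibits, measured 2007 ± 605 in non-diabetic, 2610.1 ± 269 in non-diabetic RBX, 2321 ± 282 in diabetic and 2404 ± 423 in diabetic RBX mice (mean ± SD, n = 4). It passed in none of the 7 comparisons, with an adjusted p from 0.0989 for RBX in non-diabetic to 0.967 for RBX in diabetic mice.

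Diabetes without RBX raised 36 genes, 7 of them from the interferon response, and lowered 36. Iigp1, an interferon-inducible GTPase of defence against intracellular pathogens, rose from 4960.4 ± 440.0 to 10221 ± 339 (mean ± SD, n = 4), a log2 fold change of 1.05 (SE 0.11, adjusted p = 0.00021). Igfbp3, which binds insulin-like growth factors in the circulation, rose from 575 ± 111 to 2246 ± 916 (log2 1.88 (SE 0.35, adjusted p = 0.0199)). Chil3, a chitinase-like protein secreted by macrophages, rose from 365 ± 27.7 to 1302 ± 153 (log2 1.83 (SE 0.32, adjusted p = 0.0173)). Sphkap, an anchoring protein of protein kinase A, fell from 2886 ± 792 to 1011 ± 155 (log2 -1.48 (SE 0.22, adjusted p = 0.00999)). Mylk4, a myosin light chain kinase, fell from 10901 ± 2535 to 4113 ± 657 (log2 -1.39 (SE 0.22, adjusted p = 0.00999)). The 72 genes were called out of 11042 (limma, 1682 at an unadjusted p under 0.05), 11 of the rises and 12 of the falls being over 2-fold.

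The other leading rises were F10, the coagulation factor X gene (1.54, adjusted p = 0.0414), the endothelial transcriptional repressor Bcl6b (1.27, adjusted p = 0.0264), and the translation elongation factor Eef1a2 (1.27, adjusted p = 0.0199). With them rose the endothelin receptor Ednrb (1.17, adjusted p = 0.0409), the ficolin Fcna (1.11, adjusted p = 0.0478), Ldb2 (1.02, adjusted p = 0.0277) and the interferon-inducible Rtp4 (0.99, adjusted p = 0.0429). The other leading falls were the receptor phosphatase Ptprz1 (-1.37, adjusted p = 0.0335), Sost, which encodes the Wnt antagonist sclerostin (-1.35, adjusted p = 0.0414), and the matrix protein Ecm2 (-1.32, adjusted p = 0.0206). So were Ecrg4 (-1.21, adjusted p = 0.0414), the collagen prolyl hydroxylase P3h2 (-1.12, adjusted p = 0.0173), the chloride transporter Clcn5 (-1.11, adjusted p = 0.0203), whose other probe set rose (0.37, unadjusted p = 0.0178), Ramp1, a subunit of the receptor for calcitonin gene-related peptide (-1.10, adjusted p = 0.0233), and Denn2b (-1.03, adjusted p = 0.00999). In each of these 20 genes all 4 diabetic mice lay beyond all 4 non-diabetic mice. That held for 69 of the 72 genes called and for 9.45% of all genes, where chance gives 2.86%.

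All 26 measured interferon response genes had values above 0, with a median log2 fold change of 0.54 (camera adjusted p = 5.44e-19, or 0.0619 with estimated correlation). Of them 7 rose over all genes tested and 21 rose adjusted over the list alone. Ifit1, which binds viral RNA, rose by 1.13 (adjusted p = 0.0199), Oasl2 by 0.84 (adjusted p = 0.0343) and the RNA sensor Ifih1 by 0.53 (adjusted p = 0.0264). On the same arrays the macrophage and foam cell markers had a median of 0.43 (camera adjusted p = 7.91e-10, or 0.352 with estimated correlation). Log2 cre was 0.36 higher in the diabetic mice.

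None of the 24 measured macrophage and foam cell markers passed over all genes in limma (14 at an unadjusted p under 0.05), and 4 rose adjusted over the list alone. The scavenger receptor Cd36 (0.97, adjusted p = 0.0525), the growth factor receptor Csf1r (0.39, adjusted p = 0.0759) and the Fc receptor genes Fcgr1 (0.78, adjusted p = 0.0725) and Fcer1g (0.59, adjusted p = 0.123) had the smallest p. The resident adventitial macrophage markers had a median of 0.48 over 12 genes (camera adjusted p = 0.000141, or 0.352 with estimated correlation). Fcna rose over all genes, and 7 rose and 1 fell adjusted over the list alone. The others of smallest p were the hyaluronan receptor Lyve1 (0.76, adjusted p = 0.0713), the mannose receptor Mrc1 (0.57, adjusted p = 0.0724) and the chemokine Ccl8 (0.73, adjusted p = 0.0907). The endothelial markers had a median of 0.42 over 19 genes, all above 0 (camera adjusted p = 1.85e-09, or 0.352 with estimated correlation). The tight junction gene Cldn5 rose (0.66, adjusted p = 0.0306) and 11 rose adjusted over the list alone. Next by p were Ecscr (0.71, adjusted p = 0.0525), Eng (0.67, adjusted p = 0.058) and Egfl7 (0.64, adjusted p = 0.0727).

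The contractile smooth muscle genes had a median of -0.36 over 19 genes, 16 of them below 0 (camera adjusted p = 9.4e-06, or 0.352 with estimated correlation). None passed over all genes in limma (9 at an unadjusted p under 0.05) and 6 fell adjusted over the list alone. On the same arrays adventitial fibroblast markers had a median of 0.24, with 15 of 15 above 0 (camera adjusted p = 0.000318, or 0.352 with estimated correlation), and cardiac muscle genes one of -0.34 over 5 genes (camera adjusted p = 0.102, or 0.352 with estimated correlation). Lowest in p among contractile genes were the tropomyosin Tpm1 (-0.62, adjusted p = 0.0583), Rbpms (-0.61, adjusted p = 0.0757), the potassium channel subunit Kcnmb1 (-0.90, adjusted p = 0.133) and the calponin Cnn1 (-0.61, adjusted p = 0.134). Adhesion molecules, chemokines and cytokines had a median of 0.25 over 28 genes (camera adjusted p = 0.000141, or 0.352 with estimated correlation). None passed over all genes in limma (7 at an unadjusted p under 0.05) and 6 rose adjusted over the list alone. The chemokines Ccl9 (0.85, adjusted p = 0.0527) and Ccl6 (0.92, adjusted p = 0.058), the selectin Selp (0.77, adjusted p = 0.0742) and Icam1 (0.59, adjusted p = 0.0806) came first by p.

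Lipid handling was measured by another pair of lists. On the same arrays white adipocyte genes had a median of 0.34 (camera adjusted p = 0.0746, or 0.582 with estimated correlation) and brown adipocyte genes one of 0.35 (camera adjusted p = 0.234, or 0.794 with estimated correlation). Of the 25 fatty acid oxidation genes 24 lay above 0, with a median of 0.30 (camera adjusted p = 0.000131, or 0.412 with estimated correlation). None passed in limma over all genes (5 at an unadjusted p under 0.05) or adjusted over the list alone. The smallest p were those of the lipoprotein lipase inhibitor Angptl4 (0.61, adjusted p = 0.126), the thioesterase Acot1 (0.77, adjusted p = 0.188), and the mitochondrial enzymes Acads (0.43, adjusted p = 0.195) and Acaa2 (0.60, adjusted p = 0.237). The cholesterol storage and efflux genes had a median of 0.30 over 15 genes, 13 of them above 0 (camera adjusted p = 0.000131, or 0.352 with estimated correlation). None passed in limma over all genes (4 at an unadjusted p under 0.05) and 3 rose adjusted over the list alone. Lowest in p were the apolipoprotein Apoc2 (1.31, adjusted p = 0.1), Mylip (0.31, adjusted p = 0.112), the lipid droplet protein Plin2 (0.78, adjusted p = 0.161) and the HDL receptor Scarb1 (0.32, adjusted p = 0.324).

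The count of 72 changed with single mice and with the settings, up to 1207 with array weights. It was 2 without non-diabetic mouse 1, 2 without mouse 2, 334 without mouse 3 and 23 without mouse 4. It was 223 without diabetic mouse 1, 24 without mouse 2, 1 without mouse 3 and 25 without mouse 4. With the cre control as a covariate it was 4, while all 72 kept their sign, their median size went from 0.83 to 0.68 and their median SE from 0.159 to 0.156. Of the 72 genes 66 passed in the same direction for RBX in non-diabetic mice, an overlap that the shared 4 non-diabetic arrays favour without any effect. Of the 24 named genes that passed, only Iigp1 kept its call with each array left out and in every other alternative run. Sphkap kept its call except without diabetic mouse 3. Igfbp3 lost it in 8 alternatives, one of them the mean of its probe sets (adjusted p = 0.101), and all others lost it with the cre covariate at least.

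**Figure D2:**
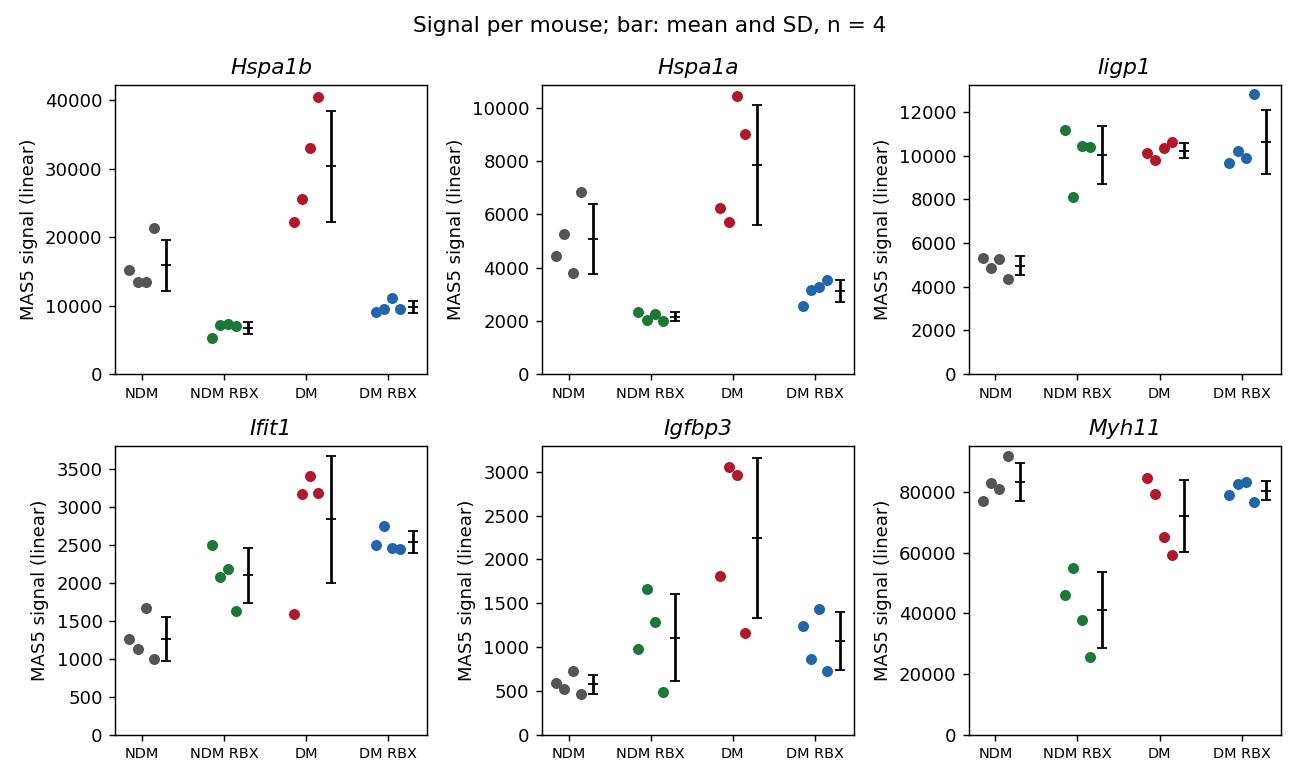
Linear signal on the y axes of 6 genes in the 4 groups on the x axes (NDM non-diabetic, DM diabetic), 1 point per mouse, with the mean and SD of the 4 mice beside them. Hspa1b and Hspa1a are lower with RBX in both kinds of mice. Iigp1 averages 4960.4 in the non-diabetic mice without RBX and 10221 in the diabetic mice. Myh11 is lowest in the non-diabetic RBX mice.

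RBX in diabetic mice lowered 4 genes, all of them for heat shock chaperones or co-chaperones, though no list of heat shock genes was set beforehand. Hspa1b, an inducible Hsp70 chaperone, fell from 30334 ± 8152 in diabetic to 9802 ± 948 in diabetic RBX mice (mean ± SD, n = 4), a log2 fold change of -1.60 (SE 0.17, adjusted p = 0.000283). Its near-identical neighbour Hspa1a, with which it can share signal on an array, fell from 7856 ± 2252 to 3133 ± 423 (log2 -1.29 (SE 0.19, adjusted p = 0.00978)). The Hsp40 co-chaperones Dnaja1 (log2 -0.85 (SE 0.14, adjusted p = 0.0269)) and Dnajb1 (log2 -0.74 (SE 0.12, adjusted p = 0.026)) fell as well. Son, a splicing cofactor, rose (log2 0.48 (SE 0.08, adjusted p = 0.0441)), but was -0.058 with the mean of its probe sets (adjusted p = 0.894). In all 5 genes the 4 mice of one group lay beyond the 4 of the other, as 6.88% of all genes did and 2.86% would by chance.

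In total 1 gene rose and 4 fell out of 11042 (limma, 1014 at an unadjusted p under 0.05), against 8 and 7 with quantile normalization and 0 and 4 with centring on the 75th percentile. The immediate early and handling response genes had a median of -0.22 over 25 genes, 19 of them below 0 (camera adjusted p = 2.54e-05, or 0.663 with estimated correlation). Of them 3 fell over all genes and 5 adjusted over the list alone. The 3 were the heat shock genes Hspa1b, Hspa1a and Dnajb1, and next by p was the flow-responsive transcription factor Klf2 (-0.56, adjusted p = 0.29).

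The unfolded protein response genes had a median of -0.25 over 21 genes, 16 of them below 0 (camera adjusted p = 4.71e-05, or 0.663 with estimated correlation). None passed in limma over all genes (8 at an unadjusted p under 0.05) and 6 fell adjusted over the list alone. The smallest p were those of the secreted factor Manf (-0.65, adjusted p = 0.206), the co-chaperone Dnajb9 (-0.40, adjusted p = 0.225), the chaperone Hspa5 (-0.39, adjusted p = 0.234) and Herpud1 (-0.56, adjusted p = 0.281). Contractile smooth muscle genes had a median of 0.22 over 19 genes, 18 of them above 0 (camera adjusted p = 2.54e-05, or 0.663 with estimated correlation). None passed in limma over all genes (3 at an unadjusted p under 0.05) or adjusted over the list alone. First by p were the transcriptional coactivator Myocd (0.42, adjusted p = 0.413), Acta2 (0.29, adjusted p = 0.418), Tpm2 (0.22, adjusted p = 0.428) and Tagln (0.23, adjusted p = 0.572). Cardiac muscle genes had a median of 0.53 over 5 genes (camera adjusted p = 0.0364, or 0.663 with estimated correlation), and on the same arrays the log2 3' to 5' ratios were higher by 0.37 for Actb and 0.23 for Gapdh (both unadjusted p = 0.0571, adjusted 0.147). Adventitial fibroblast markers had a median of 0.15 over 15 genes, 13 of them above 0 (camera adjusted p = 0.00652, or 0.698 with estimated correlation). None passed in limma over all genes (3 at an unadjusted p under 0.05) and 2 rose adjusted over the list alone. The matrix gene Dpt (0.53, adjusted p = 0.248), Pi16 (0.37, adjusted p = 0.354), the proteoglycan Dcn (0.30, adjusted p = 0.526) and Mfap5 (0.35, adjusted p = 0.58) had the smallest p.

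The count of 5 was 3 without diabetic mouse 1, 1 without mouse 3 and 1 without mouse 4. It was 1 without diabetic RBX mouse 1, 3 without mouse 2 and 2 without mouse 4. Hspa1b kept its call in every alternative run. Hspa1a lost it without diabetic mouse 3 (adjusted p = 0.0556), diabetic mouse 4 (0.0734), diabetic RBX mouse 1 (0.0678), the intensity trend (-1.29, adjusted p = 0.0608) or with the Actb ratio as a covariate (-1.10, adjusted p = 0.162). With the mean of probe sets, without the trend and with the Actb ratio Dnaja1 (-0.59, -0.85 and -0.83, adjusted p = 0.116, 0.105 and 0.18) and Dnajb1 (-0.68, -0.74 and -0.79, adjusted p = 0.0584, 0.0844 and 0.139) lost theirs. Dnaja1 lost it as well without any of diabetic mice 1, 3 and 4 and diabetic RBX mice 1, 2 and 4 (adjusted p from 0.0715 to 0.176). Dnajb1 lost it without any of these but diabetic RBX mouse 2 (from 0.0795 to 0.152), and Son did without any of the 8 mice (from 0.0719 to 0.204).

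In the non-diabetic RBX mice, whose arrays also had the highest mean cre signal, genes of contractile smooth muscle were lower and genes of the interferon response, antigen presentation, endothelium, macrophages and fat metabolism higher. These lists passed camera with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.452. Rgs4, which shortens G protein signals, fell from 3603 ± 1404 in non-diabetic to 615 ± 249 in non-diabetic RBX mice (mean ± SD, n = 4), a log2 fold change of -2.58 (SE 0.32, adjusted p = 2.27e-05). Sost fell from 13076 ± 3588 to 2452 ± 1306 (log2 -2.52 (SE 0.29, adjusted p = 1.09e-05)). Ldb3, a protein of the muscle Z-disc, fell from 8875 ± 2044 to 1694 ± 634 (log2 -2.45 (SE 0.23, adjusted p = 2.55e-06)). Retnla, a resistin-like protein secreted by alternatively activated macrophages, rose from 3239 ± 781 to 18793 ± 13169.7 (log2 2.26 (SE 0.45, adjusted p = 0.0012)). In total 1825 genes rose and 1669 fell out of 11042 (limma, 4719 at an unadjusted p under 0.05), 282 and 321 of them by over 2-fold. Both groups lay apart in 2596 of the genes called and in 27.5% of all genes, where chance gives 2.86%. On the same arrays log2 cre was 1.18 higher and the median signal was 483.9 against 394.6.

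The other leading falls were the calcium channel subunit Cacnb2 (-2.61, adjusted p = 0.00287), the serotonin receptor Htr1b (-2.56, adjusted p = 9.04e-06), and the myosin light chain kinase Mylk4 (-2.50, adjusted p = 1.84e-06). So were Sphkap (-2.49, adjusted p = 1.84e-06), the mitochondrial calcium-binding Efhd1 (-2.37, adjusted p = 1.04e-05), the matrix protein Npnt (-2.36, adjusted p = 1.88e-05) and Chmp4c (-2.34, adjusted p = 7.98e-05). The other leading rises were the kinesin family member Kif26a (2.99, adjusted p = 0.00238), the uroplakin Upk3b (2.79, adjusted p = 0.00113), the medium-chain acyl-CoA synthetase Acsm3 (2.58, adjusted p = 0.0319) and Zdhhc12 (2.45, adjusted p = 0.00555). They included Lrrn4 (2.27, adjusted p = 0.00128), Dnajc17 (2.12, adjusted p = 1.04e-05), F10 (2.01, adjusted p = 0.000235), Lrrc19 (2.00, adjusted p = 0.025), which without non-diabetic mouse 4 was 1.23 (adjusted p = 0.0933), and Fxyd3 (1.97, adjusted p = 0.000401).

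Contractile smooth muscle genes had a median of -1.001 over 19 genes (camera adjusted p = 3.55e-07, or 0.537 with estimated correlation). Of them 2 rose and 14 fell both over all genes and adjusted over the list alone. The actin-binding Synpo2 (-1.52, adjusted p = 5.12e-05) and Cnn1 (-1.44, adjusted p = 4.11e-05), the integrin Itga8 (-1.18, adjusted p = 7.23e-05) and Rbpms (-1.11, adjusted p = 7.79e-05) fell. So did the smooth muscle myosin Myh11 (-1.07, adjusted p = 0.000149), named outside the rule after its values were seen, as was the next pair of genes. Acta2 was higher (0.30, adjusted p = 0.0436) as deposited and lower after quantile normalization (-0.36, adjusted p = 0.00828). Tpm2 was higher (0.34, adjusted p = 0.00574) as deposited and -0.13 after it (adjusted p = 0.264). The other probe sets were at -2.51 (unadjusted p = 1.49e-08) and -1.61 (unadjusted p = 3.03e-05) for Acta2, and at -0.96 (unadjusted p = 1.02e-06), -0.15 (unadjusted p = 0.164) and 0.41 (unadjusted p = 0.364) for Tpm2, so the direction of these genes is not settled here. The probe sets used ranked 5 and 40 by brightness among the genes, and of the 50 brightest genes 42 rose and 0 fell (limma, median 0.63, and 0.06 after quantile normalization).

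The interferon response genes had a median of 0.71 over 26 genes, all above 0 (camera adjusted p = 1.1e-07, or 0.452 with estimated correlation). Of these 19 rose both over all genes and adjusted over the list alone. Oasl2 (1.18, adjusted p = 9.85e-05), Iigp1 (1.01, adjusted p = 7.42e-06), the immunoproteasome subunit Psmb8 (0.97, adjusted p = 3.54e-05) and Ifih1 (0.78, adjusted p = 3.96e-05) had the smallest p. Antigen presentation genes had a median of 0.67 over 13 genes (camera adjusted p = 3.55e-07, or 0.452 with estimated correlation). Of these genes 11 rose over all genes tested and 12 adjusted over the list alone. The class II genes H2-Ab1 (1.13, adjusted p = 8.16e-06), H2-Aa (0.96, adjusted p = 4.24e-06) and H2-Eb1 (0.67, adjusted p = 0.000192) and the invariant chain Cd74 (0.68, adjusted p = 0.000119) led them. Macrophage and foam cell markers had a median of 0.64 over 24 genes (camera adjusted p = 5.47e-07, or 0.537 with estimated correlation). There were 17 rises over all genes and 19 adjusted over the list alone. Among them were Cd36 (1.07, adjusted p = 0.00153), the elastase Mmp12 (1.05, adjusted p = 0.00227), Csf1r (0.73, adjusted p = 7.06e-05) and the lysozyme Lyz1 (0.75, adjusted p = 0.00155), which was 0.088 after quantile normalization (adjusted p = 0.448). Endothelial markers had a median of 0.73 over 19 genes (camera adjusted p = 5.47e-07, or 0.537 with estimated correlation). Over all genes 15 rose, and 16 rose adjusted over the list alone. They were led by Egfl7 (1.18, adjusted p = 6.28e-05), Eng (1.08, adjusted p = 8.77e-05), Ecscr (0.997, adjusted p = 0.00021) and Emcn (1.59, adjusted p = 0.000423). These lists moved on arrays whose resident adventitial macrophage markers had a median of 0.87 (camera adjusted p = 0.00503, or 0.57 with estimated correlation), with 8 of 12 rising and 1 falling. The adventitial fibroblast markers there had one of 0.50 (camera adjusted p = 0.00112, or 0.537 with estimated correlation), with 8 of 15 rising.

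Genes of fat metabolism were higher in the same mice. Fatty acid oxidation genes had a median of 0.79 over 25 genes, all above 0 (camera adjusted p = 6.61e-07, or 0.537 with estimated correlation). Of these genes 18 rose over all genes tested and 19 adjusted over the list alone. The electron transfer flavoprotein gene Etfb (1.02, adjusted p = 0.000688), the thioesterase Acot2 (0.94, adjusted p = 0.000221), Angptl4 (0.87, adjusted p = 0.00219) and Acads (0.77, adjusted p = 0.00151) had the smallest p. White adipocyte genes had a median of 0.94 over 17 genes (camera adjusted p = 0.000203, or 0.537 with estimated correlation). Over all genes 11 rose, and 13 rose and 1 fell adjusted over the list alone. Among them were the transcription factor Cebpa (0.84, adjusted p = 0.000566), the lipoprotein lipase Lpl (0.94, adjusted p = 0.00124) and the Wnt inhibitor Sfrp5 (1.05, adjusted p = 0.000566). The brown adipocyte genes had a median of 0.95 (camera adjusted p = 0.029, or 0.738 with estimated correlation). Ribosomal protein genes, which are among the brightest, had a median of 0.35 over 17 genes (camera adjusted p = 5.05e-06, or 0.537 with estimated correlation). There were 13 rises over all genes and 14 adjusted over the list alone. Rps20 (0.66, adjusted p = 0.000121), Rpl4 (0.57, adjusted p = 0.00019) and Rpl19 (0.49, adjusted p = 0.000286) were higher as deposited, and at 0.10 (adjusted p = 0.202), 0.24 (adjusted p = 0.0122) and 0.23 (adjusted p = 0.00781) after quantile normalization. Rps14 was higher as deposited (0.57, adjusted p = 0.000566) and -0.013 after quantile normalization (adjusted p = 0.897).

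With the cre control as a covariate, which differed most between these groups, limma called 0 genes (1574 at an unadjusted p under 0.05), and with the Actb ratio it called 86 rises and 88 falls. Of the 63 named genes that passed, 60 kept their call with each array left out.

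**Figure D3:**
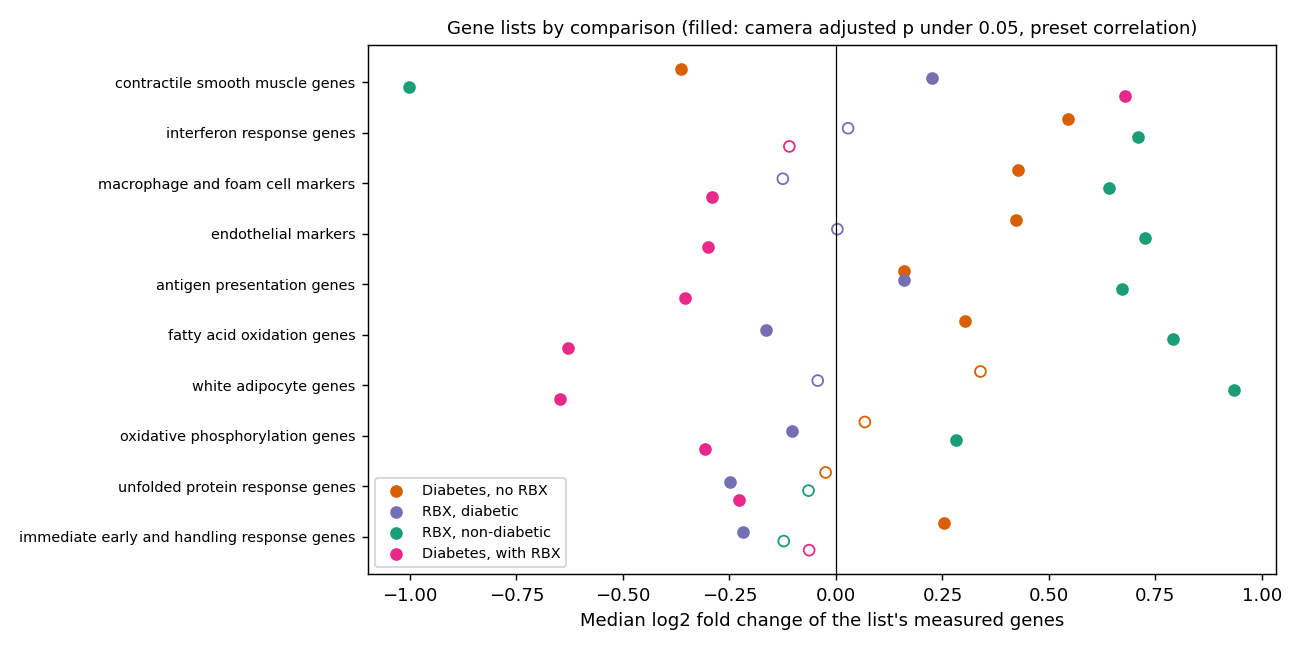
Median log2 fold change of the measured genes of 10 lists (x axis) in the 4 comparisons of 2 groups, 1 point per list and comparison, filled where the camera adjusted p with the preset correlation is under 0.05. With an estimated correlation none passes. The contractile list lies at -1.001 for RBX in non-diabetic and at 0.22 in diabetic mice. Acta2 and Tpm2 within it are higher in non-diabetic mice as deposited, and after quantile normalization Acta2 is lower and Tpm2 does not pass.

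Diabetes in mice on RBX, the same contrast in the other 8 mice, had higher medians of contractile and matrix genes and lower ones of fatty acid oxidation, oxidative phosphorylation and antigen presentation. These lists passed camera with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.554. Saa3, an acute phase serum amyloid, rose from 1595 ± 961 in non-diabetic RBX to 8227 ± 2468 in diabetic RBX mice (mean ± SD, n = 4), a log2 fold change of 2.49 (SE 0.36, adjusted p = 0.000782). Ldb3 rose from 1694 ± 634 to 6121 ± 986 (log2 1.93 (SE 0.23, adjusted p = 0.00023)). Myoz2, a calcineurin-binding protein of the Z-disc, rose from 576 ± 345 to 1728 ± 364 (log2 1.85 (SE 0.39, adjusted p = 0.00856)). Tcof1, a factor of ribosomal RNA transcription, fell from 2426 ± 552 to 1065 ± 132 (log2 -1.17 (SE 0.20, adjusted p = 0.00216)). Rgcc, a regulator of the cell cycle, fell from 16279 ± 6712 to 6164 ± 2195 (log2 -1.40 (SE 0.33, adjusted p = 0.0152)). In total 490 genes rose and 294 fell out of 11042 (limma, 2645 at an unadjusted p under 0.05), 92 and 18 of them by over 2-fold. Both groups lay apart in 666 of these genes and in 12.5% of all genes, where chance gives 2.86%.

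The other leading rises were Igsf9 (2.997, adjusted p = 0.00592), the sarcomeric actinin Actn2 (2.22, adjusted p = 0.0243), Krtap12-1 (2.21, adjusted p = 0.00713) and Rgs4 (1.84, adjusted p = 0.00258). With them rose Npnt (1.79, adjusted p = 0.00166), Tpd52l1 (1.78, adjusted p = 0.035) and Sost (1.72, adjusted p = 0.00216). The other leading falls were Apoe (-1.87, adjusted p = 0.0462), which without diabetic RBX mouse 3 was -1.06 (adjusted p = 0.0657), the adiponectin paralog C1qtnf9 (-1.47, adjusted p = 0.027), the platelet tubulin Tubb1 (-1.40, adjusted p = 0.043) and Rtn4rl1 (-1.36, adjusted p = 0.0149), whose other probe set rose (1.17, unadjusted p = 0.0297). With them fell Fcor (-1.34, adjusted p = 0.0155), Nkx2-6 (-1.32, adjusted p = 0.0392), Treml1 (-1.18, adjusted p = 0.0312) and B3galt5 (-1.14, adjusted p = 0.0492). Apoe also lost its call without diabetic RBX mouse 2 or any non-diabetic RBX mouse (adjusted p from 0.057 to 0.0873).

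Contractile smooth muscle genes had a median of 0.68 over 19 genes (camera adjusted p = 7.69e-13, or 0.554 with estimated correlation). Over all genes 13 rose, and 15 rose adjusted over the list alone. First by p were Myocd (1.42, adjusted p = 0.000174), Itga8 (1.11, adjusted p = 0.00105), Synpo2 (1.30, adjusted p = 0.00162) and Myh11 (1.02, adjusted p = 0.00182). The array mean changed by -0.26 for endothelial markers and 0.37 for skeletal muscle genes (both unadjusted p = 0.0286, adjusted 0.109) and by 0.51 for cardiac muscle genes (unadjusted p = 0.0571, adjusted 0.147). Fibrillar collagen and elastic matrix genes had a median of 0.22 over 29 genes (camera adjusted p = 0.00187, or 0.707 with estimated correlation). Of them 5 rose over all genes, and 6 rose and 1 fell adjusted over the list alone. Those of smallest p were not collagens: the proteoglycan Vcan (1.05, adjusted p = 0.00221), the matricellular Postn (0.997, adjusted p = 0.000653) and Tnc (0.86, adjusted p = 0.0095), and the crosslinking enzyme Lox (0.91, adjusted p = 0.00268). On these arrays log2 cre averaged 18.06 in the diabetic and 18.68 in the non-diabetic RBX mice.

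Fatty acid oxidation genes had a median of -0.63 over 25 genes, all below 0 (camera adjusted p = 2.19e-08, or 0.622 with estimated correlation). Of these genes 4 fell over all genes tested and 19 adjusted over the list alone. The 4 were the acyl-CoA dehydrogenase Acadl (-0.86, adjusted p = 0.0242), Etfb (-0.79, adjusted p = 0.0175), Acot2 (-0.68, adjusted p = 0.0118) and Hadha (-0.53, adjusted p = 0.042). Oxidative phosphorylation genes had a median of -0.31 over 32 genes, 30 of them below 0 (camera adjusted p = 9.17e-07, or 0.707 with estimated correlation). There were 7 falls over all genes and 9 adjusted over the list alone. Uqcrc1 (-0.72, adjusted p = 0.0151), Atp5b (-0.58, adjusted p = 0.0128), Sdhb (-0.52, adjusted p = 0.0221) and Atp5o (-0.37, adjusted p = 0.0341) came first by p. Antigen presentation genes had a median of -0.35 over 13 genes, all below 0 (camera adjusted p = 1.31e-05, or 0.554 with estimated correlation). Over all genes 5 fell, and 8 fell adjusted over the list alone. They were led by H2-Ab1 (-0.74, adjusted p = 0.00216), H2-Aa (-0.47, adjusted p = 0.00652), the immunoproteasome subunit Psmb9 (-0.74, adjusted p = 0.0222) and H2-Eb1 (-0.39, adjusted p = 0.0366). White adipocyte genes had a median of -0.65 over 17 genes (camera adjusted p = 9.73e-05, or 0.622 with estimated correlation). Of these genes 2 fell over all genes tested and 10 adjusted over the list alone. Cebpa (-0.65, adjusted p = 0.0166) and the lipase Pnpla2 (-0.66, adjusted p = 0.0461) fell, and the others of smallest p were Dgat2 (-1.15, adjusted p = 0.0549) and Lpl (-0.58, adjusted p = 0.0722). Brown adipocyte genes had a median of -0.95 on the same arrays (camera adjusted p = 0.036, or 0.749 with estimated correlation).

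The count of 784 was 500 without non-diabetic RBX mouse 4, 400 without diabetic RBX mouse 1 and 410 without diabetic RBX mouse 3. It was 48 with the cre covariate. Of the 42 named genes that passed, 20 kept their call with each array left out.

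The interaction, the RBX effect in diabetic mice minus that in non-diabetic mice, passed for 1272 genes out of 11042 (limma, 3079 at an unadjusted p under 0.05), with 665 above and 607 below 0. The RBX effect on Sost was 0.54 (SE 0.29) in diabetic and -2.52 (SE 0.29) in non-diabetic mice, a difference of 3.06 (SE 0.41, adjusted p = 0.000281). For Ptprz1 the difference was 2.76 (SE 0.40, adjusted p = 0.000516). Its mean signal was 9984 ± 3452 in non-diabetic, 2757 ± 1045 in non-diabetic RBX, 3733 ± 803 in diabetic and 6777 ± 1082 in diabetic RBX mice (mean ± SD, n = 4). It was -2.37 (SE 0.46, adjusted p = 0.00326) for Chil3 and -2.48 (SE 0.47, adjusted p = 0.00297) for F10. The other leading differences above 0 were Igsf9 (3.47, adjusted p = 0.0142), Npnt (2.76, adjusted p = 0.000568), Krtap12-1 (2.71, adjusted p = 0.0127) and Cacnb2 (2.67, adjusted p = 0.0455). After them came Ldb3 (2.65, adjusted p = 0.000178), Efhd1 (2.60, adjusted p = 0.000558), Zdhhc23 (2.60, adjusted p = 0.0238) and Sphkap (2.57, adjusted p = 0.000164). Those below 0 were Kif26a (-3.46, adjusted p = 0.0229), Apoe (-2.54, adjusted p = 0.0418), Ear3 (-2.54, adjusted p = 0.0113) and the C-type lectin Clec4e (-2.35, adjusted p = 0.00662). They included the retinol-binding Rbp7 (-2.31, adjusted p = 0.0145), Rbfox1 (-2.27, adjusted p = 0.0248), the coagulation factor F7 (-2.21, adjusted p = 0.00576) and Lrrn4 (-2.20, adjusted p = 0.0358).

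The contractile smooth muscle genes had a median difference of 1.24 over 19 genes (camera adjusted p = 3.49e-12, or 0.396 with estimated correlation). Over all genes 14 passed above 0, and 16 did adjusted over the list alone. They were led by Myocd (1.48, adjusted p = 0.000568, other probe set 0.006), Synpo2 (1.90, adjusted p = 0.000705), Cnn1 (1.74, adjusted p = 0.000724) and Tpm1 (1.26, adjusted p = 0.001). Interferon response genes had a median difference of -0.71 over 26 genes (camera adjusted p = 3.13e-08, or 0.396 with estimated correlation). Over all genes 8 passed below 0, and 14 did adjusted over the list alone. They were led by Psmb8 (-1.15, adjusted p = 0.000739, other probe set 0.23), Iigp1 (-0.96, adjusted p = 0.000935), Ifih1 (-0.75, adjusted p = 0.00365) and Oasl2 (-1.07, adjusted p = 0.0106). For fatty acid oxidation genes the median difference was -0.95 over 25 genes (camera adjusted p = 1.57e-08, or 0.452 with estimated correlation). Of them 8 passed below 0 over all genes and 18 adjusted over the list alone. First by p were Etfb (-1.27, adjusted p = 0.00641), Acot2 (-0.95, adjusted p = 0.0097), Angptl4 (-1.15, adjusted p = 0.0105) and Acadl (-1.30, adjusted p = 0.0128). For macrophage and foam cell markers it was -0.68 over 24 genes (camera adjusted p = 4.32e-08, or 0.452 with estimated correlation). Over all genes 7 passed below 0, and 17 did adjusted over the list alone. Lowest in p were Cd36 (-1.59, adjusted p = 0.00362), Csf1r (-0.64, adjusted p = 0.0106), Mmp12 (-1.27, adjusted p = 0.0176) and Fcer1g (-0.96, adjusted p = 0.023). The count of 1272 was 771 without diabetic mouse 3 and 341 with the Actb ratio as a covariate. With the cre covariate limma called 0 genes (1391 at an unadjusted p under 0.05). Of the 36 named genes that passed, 29 kept their call with each array left out.

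Diabetes averaged over mice with and without RBX raised 8 genes and lowered 2 out of 11042 (limma, 1095 at an unadjusted p under 0.05). Saa3 (1.62, adjusted p = 0.0181), the inter-alpha-trypsin inhibitor chain Itih4 (0.83, adjusted p = 0.0191), the chemokine Ccl8 (0.78, adjusted p = 0.0467) and Hspa1b (0.74, adjusted p = 0.0181) rose. So did the metallothionein Mt2 (0.74, adjusted p = 0.0137), the sodium-calcium exchanger Slc8a1 (0.68, adjusted p = 0.0441) and Iigp1 (0.57, adjusted p = 0.0102). Ppbp, a chemokine of platelets, fell from 2875 ± 1296 and 6934 ± 3104 in the non-diabetic groups to 894 ± 449 and 1949.8 ± 1329 in the diabetic ones (log2 -1.80 (SE 0.30, adjusted p = 0.0181)). Rab6b (-0.54, adjusted p = 0.0288) fell as well. Interferon response genes had a median of 0.17 over 26 genes (camera adjusted p = 2.59e-10, or 0.431 with estimated correlation). There was 1 rise over all genes and 7 adjusted over the list alone. Ifit1 (0.71, adjusted p = 0.126), Bst2 (0.54, adjusted p = 0.197) and Rtp4 (0.60, adjusted p = 0.205) were next by p. Fatty acid and triglyceride synthesis genes had a median of -0.34 over 24 genes, 20 of them below 0 (camera adjusted p = 1.28e-06, or 0.558 with estimated correlation). None passed in limma over all genes (11 at an unadjusted p under 0.05) and 4 fell adjusted over the list alone. The malic enzyme Me1 (-0.56, adjusted p = 0.137), the fatty acid synthase Fasn (-1.35, adjusted p = 0.148), Acss2 (-0.73, adjusted p = 0.235) and Agpat2 (-0.62, adjusted p = 0.321) had the smallest p. The count of 10 was 4 without non-diabetic mouse 2, 5 without mouse 4, 5 without diabetic mouse 2, 6 without mouse 3 and 4 without mouse 4. It was 1 without diabetic RBX mouse 2 or mouse 3, and without the intensity trend limma called 0 genes (1082 at an unadjusted p under 0.05). Of the 9 genes named here that passed, only Iigp1 kept its call with each array left out. Iigp1 rose by 1.05 without RBX and its interaction was -0.96, so it changed little with diabetes in mice on RBX.

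RBX averaged over diabetic and non-diabetic mice raised 1039 genes and lowered 1160 (limma, 3808 at an unadjusted p under 0.05). Hspa1b was among the leading falls (-1.41 (SE 0.12, adjusted p = 8.56e-06)), with Hspa1a (-1.25, adjusted p = 3.6e-05), Rgs4 (-1.58, adjusted p = 0.000229) and Htr1b (-1.50, adjusted p = 0.000164). With them fell Tnfrsf11b (-1.29, adjusted p = 5.07e-05), Wif1 (-1.24, adjusted p = 3.21e-05) and Pde3a (-1.23, adjusted p = 0.033). Further ones were Kcnj15 (-1.19, adjusted p = 0.000588), Chmp4c (-1.19, adjusted p = 0.00259) and Fbxo30 (-1.17, adjusted p = 0.00286). The leading rises were Retnla (1.84, adjusted p = 0.000898), Upk3b (1.57, adjusted p = 0.00959), the semaphorin receptor Plxnb3 (1.53, adjusted p = 0.00756), the platelet receptor Clec1b (1.47, adjusted p = 0.0401) and Clmn (1.47, adjusted p = 0.00653). They included the mucin Muc16 (1.41, adjusted p = 0.00293), Smim22 (1.36, adjusted p = 0.0492), the calmodulin-binding Nrgn (1.34, adjusted p = 0.000491), Shmt1 (1.32, adjusted p = 0.00709) and Dnajc17 (1.31, adjusted p = 0.000121). Antigen presentation genes had a median of 0.44 over 13 genes (camera adjusted p = 2.83e-07, or 0.452 with estimated correlation). Over all genes 10 rose, and 11 rose adjusted over the list alone. They were led by H2-Aa (0.63, adjusted p = 4.27e-05), H2-Ab1 (0.68, adjusted p = 0.000111), Cd74 (0.46, adjusted p = 0.0005) and H2-Eb1 (0.45, adjusted p = 0.000721). Immediate early and handling response genes had a median of -0.13 over 25 genes (camera adjusted p = 0.0117, or 0.682 with estimated correlation). Over all genes 1 rose and 7 fell, and 2 rose and 9 fell adjusted over the list alone. Dnajb1 (-0.45, adjusted p = 0.00151) and Klf6 (-0.44, adjusted p = 0.00285) came next after both Hsp70 genes. The count of 2199 was 12 with the cre covariate. With the Actb ratio limma called 0 genes (1562 at an unadjusted p under 0.05), where Pde3a turned to 0.47. Of the 26 named genes that passed, 23 kept their call with each array left out.

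The design also sets the RBX effect in diabetic mice against the effect of diabetes. Over the 72 genes called for diabetes without RBX, the fold changes of both comparisons had a correlation across genes of -0.596, and 53 of the genes had opposite signs. Genes are not independent replicates, and both comparisons share the 4 diabetic arrays with opposite sign. In simulated data without any effect, over the 72 genes with the smallest p, the mean correlation was -0.823 (from -0.98 to 0.195). The covariance was -0.237 against -0.214 observed, a difference of 0.0224. With the diabetic arrays divided between the comparisons in all 6 ways, other genes were used, namely those called in each division (31 and 305 genes) or, where fewer than 20 were called, the 200 with the smallest p. The correlation lay between -0.518 and 0.263 and the covariance between -0.174 and 0.0708. Of the genes raised by diabetes Hspa1b and Dnajb1 were among the 4 lowered by RBX in diabetic mice, an overlap that the shared arrays favour.

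The effects of diabetes without and with RBX share no array. Across all 11042 genes they had Pearson r = -0.355 (-0.0838 without the filter) and Spearman rho = -0.368, with genes not independent replicates. Of the 72 genes called without RBX 12 had the same sign with RBX. Of those lowered without RBX 21 were raised with it (1.6 for independent lists), and of those raised 4 were lowered (0.959). With diabetes log2 cre went from 17.49 to 17.85 without and 18.68 to 18.06 with RBX, so array brightness stays open. The RBX effects in diabetic and non-diabetic mice had Pearson r = 0.117 and Spearman rho = 0.138 across genes. Of the 4 genes lowered in diabetic mice 3, Hspa1b, Hspa1a and Dnaja1, were lowered in non-diabetic mice too (0.605 for independent lists).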

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

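The tests of array brightness, of a lower share of smooth muscle (both), of a common RBX effect, of handling and of RBX in both kinds of mice were chosen after the results were seen, while those of other divisions of the arrays and of a higher share of macrophages were set before.

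Other divisions of the same arrays were fitted in the same way. For diabetes without RBX 1 of the 35 divisions of the 8 arrays, the real one, gave as many genes (72, highest other 41), and for RBX in diabetic mice 1 of 35 did (5, highest other 0 in limma). It was 1 of 35 for RBX in non-diabetic mice (3494, highest other 247) and for diabetes with RBX (784, highest other 129). That is the smallest share possible and unadjusted, so chance is not excluded. For averaged RBX it was 1 of 100 drawn divisions (2199, highest other 961). For the interaction 3 of 100 divisions reached as many genes (1272, highest other 1703). For averaged diabetes 4 of 100 did (10, highest other 85). In both a division called more genes than the real one. The 85 points to a structure of the arrays, and the groups can be part of it. Swapping labels in 1 stratum turns an average into the interaction and the reverse. The 3 of 100 thus decide nothing on the interaction.

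The 4 non-diabetic RBX arrays stood apart, with 3494 genes called against 5 for RBX in diabetic mice. Over the 3494 the slope of the change in diabetic on that in non-diabetic mice was 0.0463 (0.0104 to 0.0951 with each array left out). Being under the required 0.5, it argued against a common RBX effect as the main cause. A smaller one stays open, as selecting these genes and array brightness can lower the slope. Array brightness before scaling stays open, since 69.6% of the called genes had a slope on the cre control in the other 12 arrays with the sign of their change, which 14 of 100 shuffles reached (highest 79.6%), and with cre as a covariate the median size of their log2 change went from 0.62 to 0.40 while its median SE rose from 0.165 to 0.332, which ended every call. A lower share of smooth muscle was first tested by contractile genes called higher, and the 2 found, Acta2 and Tpm2, came out against it; that test was set aside as void after 42 of the 50 brightest genes were seen to rise and both genes to lose their rise after quantile normalization, with other probe sets at -2.51 and -1.61 for Acta2 and -0.96, -0.15 and 0.41 for Tpm2. It stays open: a lower share of smooth muscle raises all other cell types alike, and while array means changed by 0.73 for endothelial, 0.0606 for nerve and -0.85 for B cell markers, 5 of 35 divisions of the 8 arrays moved the 10 lists outside muscle as far apart, whereas with the skeletal (-0.61) and cardiac (-0.47) lists 1 of 35 did, which would argue against it if these genes were not of smooth muscle, but the cardiac list (r = 0.825) and the fallen skeletal genes Casq1 (r = 0.796) and Pygm (r = 0.616), less so the whole skeletal list (r = 0.386), followed the contractile mean within the other 3 groups. RBX acting on the aorta of non-diabetic mice alone is also open and cannot be told apart from brightness, because the 4 arrays form 1 group.

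The 4 genes lowered by RBX in diabetic mice were heat shock genes, grouped so after they were called (Hspa1b -1.60, Hspa1a -1.29, Dnaja1 -0.85, Dnajb1 -0.74). With cre as a covariate 4 of the 4 genes passed in limma. As log2 cre was 17.85 in diabetic and 18.06 in diabetic RBX mice, this hardly tests array brightness. With the Actb ratio only Hspa1b passed. Handling at dissection stays open. The other 22 immediate early genes had a median of -0.158 (bootstrap SE over genes, not mice, 0.0533). Of them 16 lay below 0, as handling would give, but limma called 0 lower. The bound of -0.5, set after the data were seen and not reached, rests on no table. In the separate non-diabetic arrays 3 of the 4 passed lower too, Hspa1b at -1.23 (adjusted p = 5.84e-05), Hspa1a at -1.21 (adjusted p = 0.000132) and Dnaja1 at -0.38 (adjusted p = 0.046), though with cre as a covariate Hspa1b was -1.26 (adjusted p = 0.12) and Hspa1a -0.77 (adjusted p = 0.37) there. An RBX effect on these transcripts is thus open beside handling and brightness.

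Interferon response genes were higher in diabetes without RBX, with a median of 0.54. A higher share of macrophages as the whole cause was argued against, because with the macrophage markers as a covariate the median was 0.49 (0.491), 90.2% of its value. Array brightness was argued against likewise, with a median of 0.54 (0.535) and 98.2% kept under the cre covariate. The calls of single genes mostly ended, with 1 member called after either covariate (15 and 18 at an unadjusted p under 0.05) as the median SE went from 0.179 to 0.219 and 0.202, and that 1 was Iigp1, at 0.99 (adjusted p = 0.00827) and 1.04 (adjusted p = 0.00279). In mice on RBX diabetes gave no such rise, with a median of -0.11 (camera adjusted p = 0.525, or 0.927 with estimated correlation), and the mean log2 signal of the list was 10.71 in non-diabetic, 11.38 in non-diabetic RBX, 11.32 in diabetic and 11.30 in diabetic RBX mice, so whether diabetes raised these genes or the 4 non-diabetic arrays stood low stays open.

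The interaction passed for these 20 leading genes and others named above. With the cre covariate it passed for 0 genes in limma, which leaves array brightness open. It was above 0 for Igsf9 (3.47), Sost (3.06), Npnt (2.76), Ptprz1 (2.76), Krtap12-1 (2.71), Cacnb2 (2.67), Ldb3 (2.65), Zdhhc23 (2.60), Efhd1 (2.60) and Sphkap (2.57). It was below 0 for Kif26a (-3.46), Ear3 (-2.54), Apoe (-2.54), F10 (-2.48), Chil3 (-2.37), Clec4e (-2.35), Rbp7 (-2.31), Rbfox1 (-2.27), F7 (-2.21) and Lrrn4 (-2.20). Among lists the median difference was 1.24 for contractile smooth muscle genes, -1.18 for brown and -0.96 for white adipocyte genes, -0.95 for fatty acid oxidation, -0.71 for the interferon response and -0.68 for macrophage markers. It was -0.61 for antigen presentation, -0.61 for endothelial markers, -0.50 for adhesion molecules, chemokines and cytokines, -0.41 for oxidative phosphorylation, -0.39 for cholesterol storage and efflux and -0.33 for ribosomal protein genes. These 12 lists passed camera with the preset correlation and none with an estimated one (smallest adjusted p = 0.396).

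In 44 of 728 groups of 4 mice, or 6.04%, 1 mouse lay far from the other 3, where chance gives about 1 in 20. The gap to the nearest mouse over the whole range had to exceed 0.8298, which 4 normal values do in 5% of draws, in 19 array measures and 163 genes. Among array measures it was 0.908 for the contractile mean in non-diabetic mouse 3, 0.929 for the resident macrophage mean in mouse 1 and 0.890 for the T cell mean in mouse 4. It was 0.848 for the skeletal muscle mean in diabetic mouse 3, and 0.905 for the interferon mean in diabetic RBX mouse 4. In the non-diabetic mice it was, for mouse 3, 0.975 for Sost, 0.903 for Fcer1g, 0.895 for Cnn1, 0.890 for Etfb, 0.889 for Tcof1, 0.874 for Efhd1 and 0.8302 for Rpl19. It was, for mouse 4, 0.937 for Clcn5, 0.918 for Vcan and 0.878 for Acads, and for mouse 2, 0.877 for Zdhhc12. Non-diabetic RBX mice stood out with 0.939 for Dnajc17, 0.917 for Smim22 and 0.855 for Bcl6b in mouse 4, 0.936 for Ecrg4 and 0.931 for Apoc2 in mouse 2, 0.898 for Hspa1b in mouse 1 and 0.878 for Hadha in mouse 3. Diabetic mice stood out with 0.930 for Rtn4rl1, 0.898 for F10, 0.886 for Dgat2 and 0.839 for Tpm2 in mouse 4, 0.922 for H2-Ab1 and 0.904 for Ifit1 in mouse 1, and 0.894 for Ppbp in mouse 3. In diabetic RBX mouse 4 it was 0.984 for Acadl, 0.958 for Rgs4, 0.957 for Agpat2, 0.940 for Hadha, 0.917 for Rpl19, 0.889 for Plin2, 0.880 for Nrgn and 0.838 for Wif1. The others were 0.911 for Tcof1, 0.902 for Kif26a and 0.862 for Angptl4 in diabetic RBX mouse 1, and 0.905 for Lrrc19, 0.896 for Eng and 0.833 for Ifit1 in mouse 2.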

How the results depend on the processing

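Alternatives with the cre or Actb covariate or without the non-diabetic RBX arrays were chosen after seeing the data, the others before. Counts are of genes called, and where no cause is named the cause was not tested.

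For diabetes without RBX the count of 72 was 116 with the stricter filter, 43 with the mean of probe sets, 27 without the intensity trend and 1207 with array weights. It was 209 with only both groups in the fit, 4 with the cre covariate, 21 with the Actb covariate, 387 without the non-diabetic RBX arrays, and 1 to 334 leaving out each array. For RBX in diabetic mice the count of 5 was 15 with quantile normalization, 13 with the stricter filter, 2 with the mean of probe sets and 1 without the trend. It was 36 with array weights, 36 with only both groups, 16 with the cre covariate, 1 with the Actb covariate, 43 without the non-diabetic RBX arrays, and 1 to 5 leaving out each array. For RBX in non-diabetic mice the count of 3494 was 0 with the cre covariate in limma, 174 with the Actb covariate, and 2661 to 3466 leaving out each array. For diabetes with RBX the count of 784 was 387 with only both groups, where fewer arrays estimate the spread, 48 with the cre covariate, 289 with the Actb covariate, and 400 to 916 leaving out each array. For the interaction the count of 1272 was 0 with the cre covariate in limma, 341 with the Actb covariate, and 771 to 1529 leaving out each array. For averaged diabetes the count of 10 was 5 with the mean of probe sets, 0 without the trend in limma, 6 with the robust variance, and 1 to 14 leaving out each array. For averaged RBX the count of 2199 was 12 with the cre covariate, 0 with the Actb covariate in limma, and 1681 to 2345 leaving out each array. Apart from those with a block below, all other counts stayed within 1.5 times their first value.

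Directions turned for few results. With the mean of probe sets Son was -0.06 (-0.058) for RBX in diabetic mice, and Acta2 was -1.27 and Tpm2 -0.086 for RBX in non-diabetic mice. With quantile normalization Acta2 was -0.36, Tpm2 -0.13 and Rps14 -0.013 there. With it F10 for diabetes without RBX was 1.39 (adjusted p = 0.0579), Acsm3 for RBX in non-diabetic mice 2.31 (adjusted p = 0.057) and Smim22 for averaged RBX 1.18 (adjusted p = 0.0785). For RBX in non-diabetic mice, with the cre covariate Lyz1 was -0.23, Lpl -0.075, Lmod1 0.042 and Kcnmb1 0.051, and with the Actb covariate Acsm3 was -0.19. Averaged RBX gave 0.47 for Pde3a with the Actb covariate. The correlation of the diabetes effects without and with RBX, -0.355, was -0.0838 without the filter and 0.161 over the 1000 genes with the smallest averaged p, which were chosen for a shared effect. The correlation of the diabetes effect and the RBX effect in diabetic mice, -0.596, lay between -0.653 and -0.59.

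The replicate numbers are shared by all groups but did not pair the mice. Of 24 pairs of arrays with the same number 2 correlated over 0.1 (mean r = 0.0126), and 3 of 16 arrays correlated best with their own number. With the replicate number as a block the counts, in the order above, were 170, 5, 3517, 819, 1382, 12 and 2202.

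Of the other values of named genes 5262 kept their direction and side of the threshold, 118 rose above it and 828 fell below it. Of the latter 362 did so on leaving out an array, 183 with the cre and 141 with the Actb covariate. Of those of described lists 136 kept both and 34 fell below it, all with an estimated correlation. Of 56 array means none passed adjustment before or after quantile normalization, and it turned that of nerve markers for RBX in non-diabetic mice from 0.0606 to -0.00166 and that of fibroblast markers for diabetes with RBX from -0.0166 to 0.0214. Without the filter the median of all genes shifted by 0.13 (0.131) for RBX in non-diabetic mice, and no other alternative shifted it by over 0.1. Signal over background was not used here, so how it limits the dim genes is open.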

Other observations

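The genes named in this part were chosen after their values were seen, and the lists were set before; no further test was run.

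Vasoactive genes passed in single members. Diabetes without RBX raised the endothelin receptor Ednrb (1.17, adjusted p = 0.0409) and the lymphatic growth factor Vegfc (0.47, adjusted p = 0.0493) and lowered Gucy1a1 (-0.83, adjusted p = 0.0447), a subunit of the nitric oxide receptor. The list had a median of 0.05 over 19 genes (camera adjusted p = 0.517, or 0.685 with estimated correlation). In mice on RBX, diabetes lowered Vegfc (-0.89, adjusted p = 0.00023, other probe sets 0.27 and -0.42) and raised Gucy1b1 (1.07, adjusted p = 0.00313) and Gucy1a1 (0.85, adjusted p = 0.00941). Redox and NADPH oxidase genes had a median of 0.22 over 24 genes for diabetes without RBX (camera adjusted p = 0.00735, or 0.352 with estimated correlation). The plasma glutathione peroxidase Gpx3 (1.01, adjusted p = 0.0337) rose. For diabetes with RBX their median was -0.17 (camera adjusted p = 0.795, or 0.942 with estimated correlation). The hydrogen peroxide-forming oxidase Nox4 (1.14, adjusted p = 0.00266) and the metallothionein Mt2 (1.25, adjusted p = 0.00023) rose. Protein kinase C genes had a median of 0.38 over 11 genes for RBX in non-diabetic mice (camera adjusted p = 0.0507, or 0.537 with estimated correlation). Prkch (0.92, adjusted p = 0.000185) and the substrate Marcks (0.90, adjusted p = 0.00319) rose. Their interaction values were Prkch (-0.92, adjusted p = 0.00998) and Marcks (-0.98, adjusted p = 0.0388).

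For RBX in non-diabetic mice the neutrophil and blood cell list had a median of 1.22 over 7 genes (camera adjusted p = 0.0189, or 0.537 with estimated correlation), 6 of them rising. Among these were the platelet integrin Itga2b (1.22, adjusted p = 0.00126), the neutrophil S100a9 (1.40, adjusted p = 0.00209) and S100a8 (0.93, adjusted p = 0.0103), and the red cell anion exchanger Slc4a1 (1.86, adjusted p = 0.0468). In diabetic mice the median was 0.38 (camera adjusted p = 0.00933, or 0.663 with estimated correlation). None passed over all genes in limma (1 at an unadjusted p under 0.05). The resident macrophage marker Lyve1 (1.29, adjusted p = 0.000113) rose in the non-diabetic RBX mice. The matrix genes Vcan (-1.53, adjusted p = 1.21e-05), Lox (-1.12, adjusted p = 7.39e-05) and Postn (-1.01, adjusted p = 5.81e-05) fell there, while the collagen-binding Fmod (1.15, adjusted p = 0.000266) rose.

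Cell cycle genes had a median of 0.27 over 24 genes for diabetes without RBX (camera adjusted p = 0.0014, or 0.352 with estimated correlation). For RBX in diabetic mice it was -0.17 (camera adjusted p = 0.00933, or 0.663 with estimated correlation). Matrix proteases and inhibitors had a median of 0.27 over 22 genes for diabetes without RBX (camera adjusted p = 0.00933, or 0.352 with estimated correlation). Cholesterol synthesis genes had one of -0.18 over 18 genes for averaged diabetes (camera adjusted p = 0.00501, or 0.537 with estimated correlation). The remaining lists passed in none of the comparisons, and each is given where its p was smallest. Averaged diabetes gave a median of -0.20 over 6 nerve and Schwann cell markers (camera adjusted p = 0.0784, or 0.558 with estimated correlation) and -0.47 over 4 B cell and plasma cell markers (camera adjusted p = 0.171, or 0.558 with estimated correlation). It gave -0.05 over 10 osteochondrogenic genes (camera adjusted p = 0.443, or 0.558 with estimated correlation) and -0.01 over 16 glycolysis genes (camera adjusted p = 0.226, or 0.558 with estimated correlation). RBX in diabetic mice gave 0.10 over 23 insulin and IGF signalling genes (camera adjusted p = 0.102, or 0.663 with estimated correlation) and 0.18 over 18 glucocorticoid response genes (camera adjusted p = 0.253, or 0.784 with estimated correlation). For it the median was 0.06 over 4 sex-specific genes (camera adjusted p = 0.37, or 0.698 with estimated correlation). Diabetes without RBX gave -0.21 over 15 circadian clock genes (camera adjusted p = 0.0793, or 0.412 with estimated correlation) and -0.40 over 4 skeletal muscle genes (camera adjusted p = 0.109, or 0.352 with estimated correlation). Diabetes with RBX gave -0.21 over 5 T cell markers (camera adjusted p = 0.554, or 0.866 with estimated correlation).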
